A study of Homo sapiens with 12 samples.

How the data were processed

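MicroRNAs (miRNAs) were measured in 12 samples of total RNA from cells labelled Caco-2, a human colon cancer line. Each sample was hybridised to its own 1-colour miRNA array, and there were 3 arrays in each of 4 groups: control cells at 12 h, cells treated with galectin-9 (Gal-9, a sugar-binding protein) at 12 h, control cells at 24 h and Gal-9-treated cells at 24 h. Group, time and replicate number were read from the sample titles. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The Gal-9 dose of each array is not stated, the treatment protocol in the labels names a longer culture than the titles do, and the extraction protocol speaks of serum although the samples are named as cells.

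Per the file headers, each scanner file gives the foreground intensity of every spot as the mean and as the median over its pixels, and the median local background intensity, on a linear scale and without correction. One channel was filled, and its column names give a shorter wavelength than the dye Cy5, named in the labels, is read at. Every array had 3200 spots, of which 2019 were miRNA probes, 925 were blank, 24 were negative controls and 16 were spike controls; no spot carried a scanner flag. The deposited table of the whole series holds intensity values that ranked almost exactly as the mean foreground (lowest rank correlation 0.999999) and had a median of about 230 on every array. These deposited values were therefore taken as mean foreground made equal in distribution between arrays, on a linear scale and without background correction; the software used by the authors is not given in the sources used here.

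The mean foreground was corrected against the local background by normexp with an offset of 50, over all spots, with limma 3.58.1 in R 4.3.3. Control spots were then left out and the 2019 probes were quantile-normalized between the 12 arrays and put on the log2 scale. A probe was called detected on an array when its median foreground was above the mean plus 2 SD of the blank spots of that array, and 1507 probes detected on all 3 arrays of at least 1 group were tested. The foreground column for detection had not been fixed in advance. The median was chosen after the numbers of calls with the mean column had been seen, because the SD of the mean foreground over blank spots reached 288 on 1 control array at 24 h and 42.1 on 1 control array at 12 h, against 11.4 to 18.6 for the median column. Detection on the mean column is among the alternatives. A stricter measure of signal was the mean plus 2 SD of the negative control spots, which 204 probes passed on all 12 arrays. One probe, miR-4454, was at the scanner's limit of 65535 on all 12 arrays and has only a bound there.

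One limma model with 4 group means was fitted to all 12 arrays, without a replicate block (lmFit and eBayes, 8 residual and 6.24 prior degrees of freedom). Tests were two-sided, p was adjusted by Benjamini-Hochberg over the 1507 probes, and a probe was called at an adjusted p below 0.05. The comparisons were 6: Gal-9 against control at each time, their mean, the change of the Gal-9 effect between the times, and 24 h against 12 h in each treatment. Log2 changes are given with the standard error (SE) of the model.

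The named miRNAs were chosen by a rule fixed before the data were examined: in each comparison the 12 largest increases and the 12 largest decreases among the calls whose groups of arrays did not overlap. Where fewer than 5 passed in a direction, the 5 smallest unadjusted p-values in that direction were taken as values that did not pass. Members of the lists could be named as examples. The lists, also fixed before the data were examined, were the let-7 family, the miR-17-92 clusters, the miR-200 family, intestinal epithelium, p53-responsive miRNAs, the miR-15/16, miR-29, miR-30 and miR-181 families, the miR-23/27/24 and miR-183/96/182 clusters, colorectal oncomiRs, colorectal tumour suppressors, NF-kB and inflammation, cell stress, the 14q32 cluster, the C19MC cluster and the X-linked cluster of miR-506 to miR-514a. The list named after the miR-200 family also held miR-205-5p, which is not of that family. Markers of 7 other cell types or fluids were fixed with the lists, as were the miRNAs numbered 3000 and above, later database entries taken as a technical contrast. List names were matched literally to probe names, so 23 of 181 list names, 10 of them in the 14q32 list, found no probe and are left out of the tallies. For 20 of the 23 a tested probe carried the name without its arm, such as miR-410, miR-494, miR-210 and miR-215; matching these too, chosen after seeing the data, is among the alternatives. 15 probes carry several names. Lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over 25 lists. Of the calls with the preset correlation, those of the miR-17-92 clusters, the miR-30 family, the 14q32 cluster and the miRNAs numbered 3000 and above held with an estimated correlation at both times, on the quantile scale. With arrays centred on the median the miR-30 call was lost at both times (adjusted p = 0.300 and 0.379) and the 14q32 call at 24 h (adjusted p = 0.0943).

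On simulated arrays with 200 of 1507 probes changed, the model without the quantile step recovered the simulated sizes, with 5.39% of calls false for the averaged effect. With the quantile step, 69% of the changes of 0.5 and 97% of the changes of 1 (log2) were called for the comparison at 12 h, with median estimates shrunk to 0.43 and 0.86 and 7.26% of calls false. At 24 h 61% and 97% were called, with 5.39% false. For the averaged effect 90% and 99% were called and 13.7% of calls were false, since normalizing arrays on which many probes changed moved unchanged probes slightly. Rises and falls were simulated in equal number and size among randomly drawn probes. The false share where rises are larger than falls, or lie in brighter probes, was not measured. For the change of the effect between the times 27% and 81% were called (4.42% false), for the times in control cells 62% and 98% (6.98% false), and for the times in treated cells 51% and 94% (7.05% false). A single simulated data set with no change gave 0 calls in all 6 comparisons. It had independent noise and no quantile step, so it does not test errors from that step or from noise shared between probes.

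Precision is limited by the 3 arrays per group and by signal: between 799 and 1746 probes per array were above the blank spots, and between 257 and 455 were above the negative controls. Alternatives fixed before the data were examined were no background correction, subtraction of the blank signal, centring on the median, cyclic loess, no filter, detection on all 12 arrays, the deposited values, only the arrays compared, the replicate number as a block, a variance trend with a robust prior, array weights and leaving out each array. Chosen after seeing the data were the median foreground, detection on the mean foreground or against the negative controls, slide position, list names without the arm, and scaling to the spike controls. For spike scaling the mean blank signal was subtracted, with a floor, in place of normexp. Each array was then shifted by its mean log2 spike signal, and the quantile step was left out. A call of a probe or list lost under spike scaling may come from any of these steps. Here and in the alternative with the blank signal subtracted, the blank signal was taken from the mean foreground column. The SD of that column over blank spots reached 288 on 1 control array at 24 h, so values that include this array may be affected. No slide number or scan date was found in the files used, so neither could serve as a block; only the position on the slide was given. For neighbouring miRNA genes a gene list of assembly GRCh38.p14 was used for names and neighbours only. Figures were drawn with matplotlib 3.10.9.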

Results

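The experiment asked how Gal-9 acts on colon cancer cells, and these arrays covered its miRNA part in cells labelled Caco-2. Arrays of 1 group correlated at 0.945 to 0.971 over the 1507 tested probes, and arrays of control and Gal-9-treated cells at the same time at 0.924 to 0.969. The first principal component held 24.3% of the variance and separated the 6 Gal-9 arrays from the 6 control arrays. On the second, with 17.1%, control replicates 1 and 2 and Gal-9 replicate 1 at 12 h stood apart from all other arrays. The median foreground intensity of the miRNA probes ranged from 210 to 241 between arrays, against a mean of 157 to 191 over the blank spots. Every control array lay at position 1 or 3 of its slide and every Gal-9 array at position 2 or 4, so treatment and odd or even position cannot be told apart. The spike control spots, which carry added RNA rather than RNA of the cells, were dimmer on the Gal-9 arrays by 0.16 and 0.17 on the log2 scale for their 2 kinds (log2 changes -0.16 and -0.17, adjusted p = 0.0888 for both, limma).

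After 12 h with Gal-9, several miRNAs with high database numbers were brighter than in control cells, and members of the miR-17-92 clusters were among the dimmer ones. miR-3687 showed the largest rise, from a log2 intensity of 8.23 ± 0.22 to 10.04 ± 0.14 (SD, n = 3 each), a 3.49-fold change. miR-3960 rose 2.95-fold, miR-4739 2.85-fold, miR-3196 2.52-fold, miR-1246 2.31-fold and miR-762 2.14-fold. Among the lower miRNAs, miR-425-5p fell by 0.77 on the log2 scale, from 9.72 ± 0.12 to 8.95 ± 0.06 (SD, n = 3 each), and miR-20a-5p, a member of the growth-promoting miR-17-92 clusters, fell by 0.75. These falls are relative to the quantile scale. Scaled to the spike controls, the median of all probes lay 0.18 higher with Gal-9 and no probe was called lower. That scaling also changed the background correction and left out the quantile step, so the lost calls cannot be ascribed to the scale alone.

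In numbers, 82 of 1507 probes were called at 12 h, 53 higher and 29 lower, by limma with Benjamini-Hochberg adjustment, and 214 had an unadjusted p below 0.05. The 2 groups of arrays did not overlap for any of the 82 called probes; over all tested probes they did not overlap for 17.6%, where chance gives 10%. That share is not specific to Gal-9, since it was 16.7% between the times in control cells, where limma called 0 probes. Centring arrays on the median of probes detected on all 12 gave 64 higher and 5 lower, cyclic loess 63 and 7, subtraction of the blank signal 25 and 2, the authors' deposited values 62 and 48, and spike scaling 43 and 0. The named increases were completed by miR-4294 (log2 change 1.02, SE 0.16), miR-1234-5p (0.99, SE 0.15), miR-1915-3p (0.91, SE 0.13), miR-4508 (0.88, SE 0.13), miR-3621 (0.87, SE 0.12) and miR-4466 (0.87, SE 0.15). Adjusted p ran from 1.7e-06 for miR-3687 to 0.0123 for miR-4739, whose control arrays at 12 h spread widely (SD 0.93).

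The named decreases at 12 h were smaller than the increases. miR-125a-3p fell by 0.63 on the log2 scale, miR-25-3p by 0.62, miR-376a-3p by 0.59, miR-187-5p by 0.57, let-7i-5p by 0.53, miR-20b-5p by 0.53, let-7g-5p by 0.52 and miR-361-5p by 0.50, with adjusted p from 0.00190 for miR-25-3p to 0.0427 for let-7i-5p. A further 2 named probes were close to background. miR-1277-5p was above the blank spots on the 3 control arrays and on 0 Gal-9 arrays at 12 h, and its fall (adjusted p = 0.0492, limma) is given without a size. miR-4999-5p was above them on 3 control arrays and 1 Gal-9 array at 12 h, so its fall (adjusted p = 0.0199) is given without an exact size. Neither was above the negative controls on any array.

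The miR-17-92 clusters, whose members are driven by MYC and promote cell growth, were lower as a list at 12 h on the quantile scale. Of 13 tested members 0 rose and 6 fell (8 adjusted over the list alone), with a median log2 change of -0.34 that became 0.0059 when scaled to the spike controls (camera adjusted p = 5.5e-08, and adjusted p = 0.0211 with an estimated correlation). Besides miR-20a-5p, miR-20b-5p and miR-25-3p, miR-17-5p fell by 0.49 on the log2 scale, miR-106a-5p by 0.49 and miR-93-5p by 0.47. In the let-7 family, known to restrain growth genes such as RAS, 3 of 8 members are counted here as lower (5 adjusted over the list alone), let-7e-5p with let-7g-5p and let-7i-5p; the median change was -0.40, and 0.08 with spike scaling. Its call (camera adjusted p = 0.00140) was lost with an estimated correlation (adjusted p = 0.128 with an estimated correlation).

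The 14q32 cluster, a large imprinted group of miRNA genes, had 4 of 22 members lower at 12 h and 0 higher (4 lower adjusted over the list alone). miR-376a-3p, miR-376c-3p (fell by 0.50), miR-377-3p (fell by 0.34) and miR-654-3p (fell by 0.34) were the members called, and the list median was -0.18, or 0.07 with spike scaling (camera adjusted p = 5.27e-05, and adjusted p = 0.0174 with an estimated correlation). In the miR-30 family 0 of 5 members passed over all probes and 5 adjusted over the list alone, with a median of -0.37 (0.05 with spike scaling; camera adjusted p = 0.000481, and adjusted p = 0.0211 with an estimated correlation). The miR-15/16 family, known to repress BCL2, had 0 of 7 members called (4 lower adjusted over the list alone) and a median of -0.31 (-0.06 with spike scaling; camera adjusted p = 0.000545, and adjusted p = 0.0894 with an estimated correlation). In the miR-23/27/24 clusters, miR-27a-3p (-0.46) and miR-27b-3p (-0.49) were the 2 of 5 members called (3 adjusted over the list alone), with a list median of -0.34 and of -0.04 with spike scaling (camera adjusted p = 0.00625, and adjusted p = 0.186 with an estimated correlation). Colorectal oncomiRs had 2 of 13 lower, miR-17-5p and miR-20a-5p (3 adjusted over the list alone), and a median of -0.16 that was 0.18 with spike scaling (camera adjusted p = 0.00536, and adjusted p = 0.246 with an estimated correlation).

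Several of these list calls at 12 h did not pass under other scales. With arrays centred on the median, the calls were lost for let-7 (median -0.14, camera adjusted p = 0.291; range over its alternatives 0.000459 to 0.792), miR-30 (-0.16, 0.300; 3.6e-05 to 0.792), miR-23/27/24 (-0.25, 0.231; 0.00281 to 0.618) and the oncomiRs (-0.05, 0.286; 0.000705 to 0.820). The oncomiR call was also lost with cyclic loess (median -0.10, adjusted p = 0.0966). With only probes detected on all 12 arrays, a filter and not a scale, the miR-23/27/24 median stayed at -0.34 with an adjusted p of 0.0702. With spike scaling none of the lists called at 12 h kept its call, the miR-17-92 clusters having an adjusted p of 0.618 (range 1.32e-10 to 0.618), the miR-15/16 family 0.469 (6.51e-05 to 0.469) and the 14q32 cluster 0.618 (3.75e-08 to 0.618).

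Among the miRNAs numbered 3000 and above, most of the calls at 12 h were higher. Of 613 tested, 37 rose and 2 fell (40 and 2 adjusted over the list alone), although their median change was only 0.02 and became -0.01 with arrays centred on the median (camera adjusted p = 0.000545, and adjusted p = 0.0153 with an estimated correlation; camera adjusted p = 0.469 with spike scaling, range over its alternatives 5.23e-12 to 0.469). Leaving out Gal-9 replicate 2 at 12 h lowered the count of called probes from 82 to 54, and fitting only the arrays of these 2 groups gave 52. The position on the slide could not be separated from the treatment.

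After 24 h miRNAs again differed between Gal-9-treated and control cells, 34 of them higher and 12 lower at both times. miR-1246, a short RNA listed among p53-responsive miRNAs, rose 2.63-fold, from 8.55 ± 0.10 to 9.95 ± 0.03 (log2 intensity, SD, n = 3 each). miR-3687 rose 2.45-fold, miR-4294 2.09-fold, miR-3196 1.96-fold, miR-1234-5p 1.90-fold, miR-762 1.89-fold and miR-3960 1.89-fold. miR-20b-5p fell by 0.72 on the log2 scale, miR-27a-3p by 0.63, miR-20a-5p by 0.62, miR-16-5p by 0.61 and miR-17-5p by 0.56. These falls too are given relative to the other probes of the array. Scaled to the spike controls, the median of all probes lay 0.32 higher with Gal-9 and no probe was called lower. The value of 0.32 may be affected by 1 control array at 24 h, whose subtracted blank spots spread widely (SD 288).

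At 24 h, 56 of 1507 probes were called, 39 higher and 17 lower (limma, Benjamini-Hochberg), and 172 had an unadjusted p below 0.05. The groups did not overlap for any of the 56, and for 17.5% of all tested probes, where chance gives 10% and the times in control cells gave 16.7%. The split was 41 higher and 36 lower in the authors' deposited values, 44 and 2 with centring on the median, 45 and 6 with cyclic loess, and 24 and 0 with spike scaling. The remaining named increases were miR-6126 (log2 change 0.89, SE 0.11), miR-4787-5p (0.82, SE 0.11), miR-204-3p (0.78, SE 0.11), miR-4466 (0.73, SE 0.15) and miR-4508 (0.72, SE 0.13). The remaining named decreases were miR-10a-5p (-0.53, SE 0.10), which lies in a HOX gene cluster like miR-196a-5p (-0.49, SE 0.10), then miR-376c-3p (-0.50, SE 0.12), miR-376a-3p (-0.50, SE 0.13), miR-93-5p (-0.48, SE 0.10), miR-191-5p (-0.47, SE 0.09) and miR-425-5p (-0.45, SE 0.10). Adjusted p among the named miRNAs ran from 2.59e-05 for miR-1246 to 0.0430 for miR-376a-3p.

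The miR-17-92 clusters had 5 of 13 members lower and 0 higher at 24 h (8 lower adjusted over the list alone), and the median change was -0.34 (camera adjusted p = 6.07e-09, and adjusted p = 0.0228 with an estimated correlation). The let-7 family had 0 of 8 members called over all probes and 4 lower adjusted over the list alone, with a median of -0.38 (camera adjusted p = 7.74e-05, and adjusted p = 0.0492 with an estimated correlation). In the miR-15/16 family miR-16-5p was the 1 member of 7 called (5 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 5.86e-05, and adjusted p = 0.0434 with an estimated correlation). The 14q32 cluster had 3 of 22 members lower (6 adjusted over the list alone), miR-376a-3p, miR-376c-3p and miR-495-3p, and a median of -0.12 that was 0.06 with spike scaling (camera adjusted p = 0.000330, and adjusted p = 0.0251 with an estimated correlation). The miR-30 family had 0 of 5 called (4 adjusted over the list alone) and a median of -0.32, or -0.07 with spike scaling (camera adjusted p = 0.00261, and adjusted p = 0.0434 with an estimated correlation). The miR-23/27/24 clusters had 1 of 5 lower, miR-27a-3p (3 adjusted over the list alone), with a median of -0.32 and of 0.04 with spike scaling (camera adjusted p = 0.00481, and adjusted p = 0.149 with an estimated correlation). Colorectal oncomiRs had 2 of 13 lower (4 adjusted over the list alone) and a median of -0.12, or 0.07 with spike scaling (camera adjusted p = 0.000809, and adjusted p = 0.164 with an estimated correlation). Of the endothelial markers miR-126-3p fell by 0.40 (1 of 2 members, also 1 adjusted over the list alone; camera adjusted p = 0.0407, and adjusted p = 0.169 with an estimated correlation).

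At 24 h centring on the median ended the calls of miR-30 (median -0.21, camera adjusted p = 0.379; range over its alternatives 0.000217 to 0.379), miR-23/27/24 (-0.11, 0.235; 0.00201 to 0.235) and 14q32 (-0.09, 0.0943; 4.44e-06 to 0.0943). It also ended those of the oncomiRs (0.0993; 0.000181 to 0.226) and the endothelial markers (0.0993; 0.00498 to 0.0993), whose medians hardly moved (-0.12 and -0.38). Cyclic loess ended the calls of miR-30 (median -0.24, adjusted p = 0.0723) and miR-23/27/24 (-0.08, 0.0645). With only probes detected on all 12 arrays the miR-23/27/24 median stayed at -0.32 with an adjusted p of 0.0690. Spike scaling ended those of miR-30 (0.361), miR-23/27/24 (0.194), the oncomiRs (0.226) and 14q32 (0.0627).

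Of the 613 miRNAs numbered 3000 and above, 29 rose and 0 fell at 24 h (32 rose and 1 fell adjusted over the list alone), with a median of 0.02 that was -0.02 with arrays centred on the median (camera adjusted p = 0.000809, and adjusted p = 0.0195 with an estimated correlation). The count at 24 h depended on single arrays: it was 28 without Gal-9 replicate 1, 31 without control replicate 2 and 32 without control replicate 3. With the mean blank signal subtracted instead of normexp, 2 probes were called, miR-3687 (log2 change 1.53) and miR-1246 (1.65). That subtraction, too, includes the control array at 24 h with widely spread blank spots.

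Averaged over both times, the Gal-9 effect was largest for miR-3687 (2.92-fold higher), miR-4739 (2.54-fold), miR-1246 (2.46-fold), miR-3960 (2.36-fold) and miR-3196 (2.22-fold). miR-4294, miR-762, miR-1234-5p, miR-6126, miR-4787-5p, miR-4466 and miR-4508 followed with rises between 1.74-fold and 2.06-fold. The largest decreases were those of miR-20a-5p (log2 change -0.69, SE 0.08), miR-20b-5p (-0.62, SE 0.08), miR-425-5p (-0.61, SE 0.07), miR-27a-3p (-0.55, SE 0.08) and miR-376a-3p (-0.54, SE 0.09), all relative to the quantile scale. Scaled to the spike controls, the median of all probes was 0.27 higher with Gal-9, 66 probes were called higher and 0 lower. Standard errors of the list members were larger with this scaling, such as 0.17 instead of 0.08 for miR-20a-5p. A lost call may therefore also reflect lower precision.

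**Figure D1:**
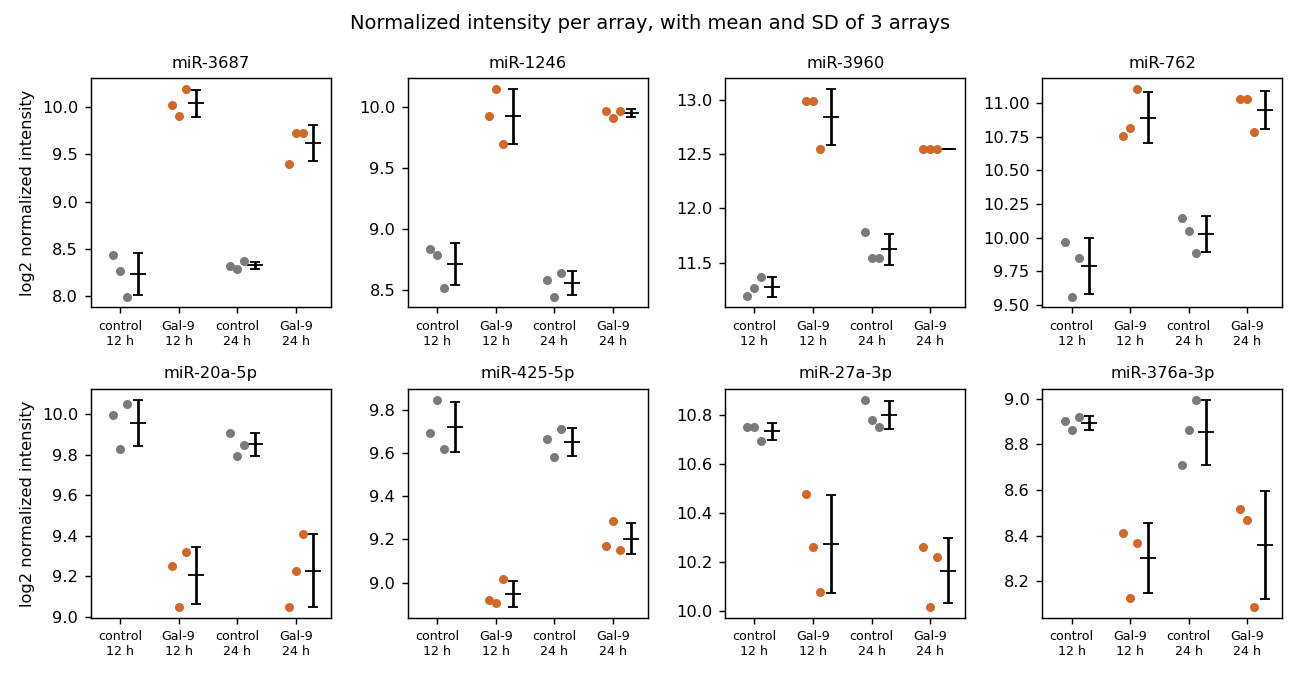
Normalized log2 intensity (vertical axis) of 8 named miRNAs on each of the 12 arrays (points), with the mean and SD of the 3 arrays of each group (black bars), for control and Gal-9-treated cells at 12 h and 24 h. miR-3687 rose from 8.23 to 10.04 and miR-20a-5p fell from 9.96 to 9.21 at 12 h on the quantile scale. The fall of miR-20a-5p was not called when arrays were scaled to the spike controls. Its averaged log2 change was then -0.37 (SE 0.17), against -0.69 (SE 0.08) on the quantile scale.

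For the averaged effect 130 probes were called, 69 higher and 61 lower (limma, Benjamini-Hochberg), 255 had an unadjusted p below 0.05, and 103 of the 130 did not overlap at either time. Of all 1507 tested probes, 119 (7.9%) did not overlap at either time and changed in the same direction at both. The split was 68 higher and 20 lower with centring on the median, 76 and 31 with cyclic loess, 53 and 23 with the blank signal subtracted and 75 and 79 in the authors' deposited values. The other named decreases were miR-17-5p (log2 change -0.52), miR-10a-5p (-0.51), miR-187-5p (-0.51), miR-25-3p (-0.51), let-7i-5p (-0.51), miR-376c-3p (-0.50) and miR-93-5p (-0.47). Adjusted p among the named miRNAs ran from 1.25e-07 for miR-3687 to 0.00381 for let-7i-5p.

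By list, 8 of 13 members of the miR-17-92 clusters were lower for the averaged effect and 0 higher (9 lower adjusted over the list alone; camera adjusted p = 3.61e-10, and adjusted p = 0.0102 with an estimated correlation). The let-7 family had 4 of 8 lower (6 adjusted over the list alone), with let-7f-5p falling by 0.55 (camera adjusted p = 4.87e-05, and adjusted p = 0.0472 with an estimated correlation). The miR-15/16 family had 4 of 7 lower (6 adjusted over the list alone), miR-15a-5p, miR-15b-5p, miR-16-5p and miR-424-5p (camera adjusted p = 1.45e-05, and adjusted p = 0.0325 with an estimated correlation). The miR-30 family had 4 of 5 lower (4 adjusted over the list alone; camera adjusted p = 0.000109, and adjusted p = 0.0163 with an estimated correlation). The 14q32 cluster had 8 of 22 lower (10 adjusted over the list alone; 9 lower with names also matched without the arm, median -0.12 instead of -0.17; camera adjusted p = 9.54e-06, and adjusted p = 0.0102 with an estimated correlation). The miR-23/27/24 clusters had 3 of 5 lower, among them miR-24-3p with a fall by 0.33 (3 adjusted over the list alone; camera adjusted p = 0.00172, and adjusted p = 0.122 with an estimated correlation). Colorectal oncomiRs had 5 of 13 lower, with miR-21-5p, which is raised in many tumours, falling by 0.45 (6 adjusted over the list alone; camera adjusted p = 0.000478, and adjusted p = 0.137 with an estimated correlation). Centring on the median ended the averaged calls of let-7 (median -0.19, adjusted p = 0.0815; range over its alternatives 5.03e-06 to 0.161), miR-30 (-0.18, 0.231; 7.98e-06 to 0.504), miR-23/27/24 (-0.18, 0.118; 0.000448 to 0.199) and the oncomiRs (-0.09, 0.118; 5.8e-05 to 0.496). Spike scaling ended the same 4 (0.161, 0.504, 0.199 and 0.496) and that of 14q32 (0.119; 6.3e-09 to 0.119). With only probes detected on all 12 arrays the miR-23/27/24 median stayed at -0.33 with an adjusted p of 0.0568. All 7 of these directions are relative to the quantile scale: with spike scaling the list medians were -0.02 for let-7, -0.05 for miR-17-92, -0.16 for miR-15/16, -0.01 for miR-30, 0.01 for miR-23/27/24, 0.13 for the oncomiRs and 0.06 for 14q32, and relative to the shift of all probes they were -0.29, -0.32, -0.43, -0.28, -0.26, -0.14 and -0.21. That shift was 0.27 over all 1507 tested probes, most of them not above the negative controls on every array. Over the 204 probes that were, the spike-scaled median was 0.16, and relative to it the falls are smaller.

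**Figure D2:**
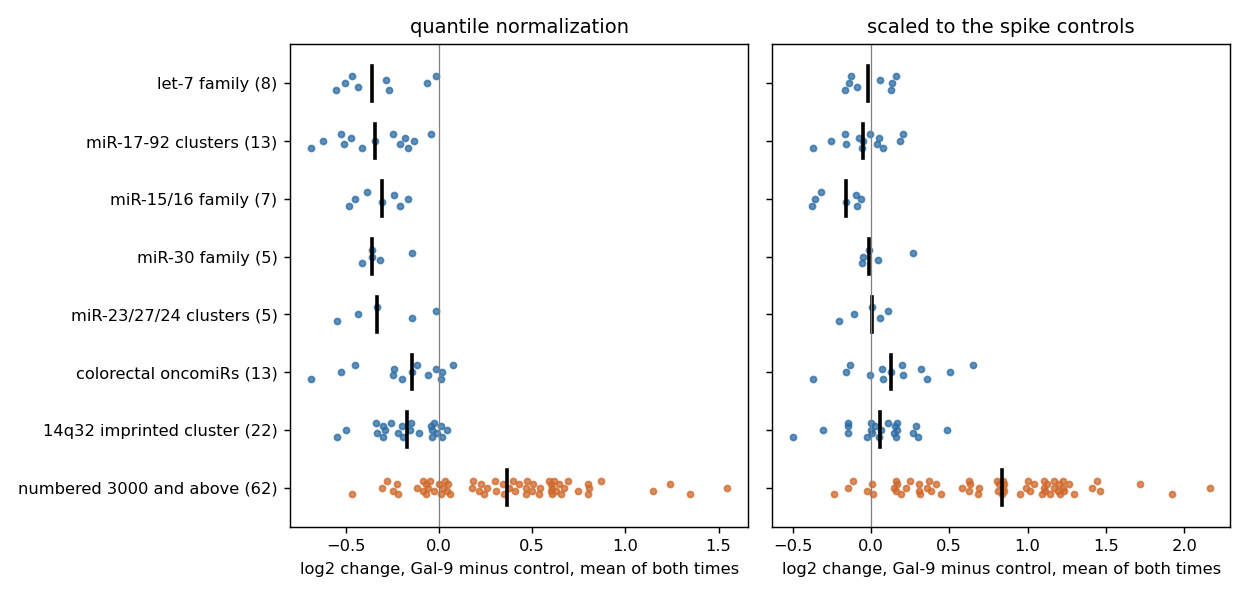
Log2 change, Gal-9 minus control, averaged over both times (horizontal axes), of the members of 7 miRNA lists and of the 62 miRNAs numbered 3000 and above that were above the negative controls on all 12 arrays (points; black lines are medians), after quantile normalization (left) and after scaling to the spike controls (right). The median of the high-numbered miRNAs was 0.36 on the left and 0.84 on the right, while that of the let-7 family was -0.36 on the left and -0.02 on the right, and those of the miR-23/27/24, oncomiR and 14q32 lists turned from below to above 0.

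The miRNAs numbered 3000 and above had 48 of 613 higher and 2 lower (48 and 2 adjusted over the list alone), with a median of 0.02 that was -0.02 with arrays centred on the median (camera adjusted p = 7.47e-05, and adjusted p = 0.00724 with an estimated correlation). The miR-200 family, intestinal epithelium, p53-responsive miRNAs, the miR-29 and miR-181 families, the cluster of miR-183, miR-96 and miR-182-5p, colorectal tumour suppressors, NF-kB and inflammation, and cell stress did not pass as lists with camera, with adjusted p of 0.166, 0.0642, 0.756, 0.756, 0.195, 0.195, 0.0616, 0.195 and 0.943. With fry, which does not set the members against the other probes, adjusted p was below 0.05 for the miR-200 family (0.0232), the intestinal list (0.00175), the cluster of miR-182-5p (0.00175), the tumour suppressors (0.0115) and the NF-kB list (0.0398). At 12 h fry also passed the miR-200 family (0.0461) and the intestinal list (0.0116). At 24 h it passed the intestinal list (0.0167), the cluster of miR-182-5p (0.00350) and the tumour suppressors (0.0278). Some passed with camera under alternatives: the averaged intestinal list (lowest adjusted p 0.0234, range to 0.496), tumour suppressors (0.0409 to 0.192) and endothelial markers (0.0233 to 0.144). So did the intestinal list at 12 h (0.0404 to 0.792), and at 24 h the tumour suppressors (0.0359 to 0.217) and the cluster of miR-182-5p (0.0257 to 0.379). Single members of these lists did pass: miR-10a-5p, miR-107 (fell by 0.39), miR-182-5p (fell by 0.24), miR-126-3p (fell by 0.36), miR-9-5p (fell by 0.30), miR-21-5p (fell by 0.45), miR-1246 (rose by 1.30) and miR-663a (rose by 0.32). Adjusted over the list alone, 2 members of the intestinal list, 1 of the miR-182-5p cluster, 1 of the tumour suppressors and 2 of the NF-kB list were lower, 1 of the p53 list was higher and 1 lower, and 1 of the stress list was higher. For the p53 list the median (-0.03) and the mean (0.05) differed in sign. With only positions 1 and 2 of the slides 41 probes were called and with only positions 3 and 4 there were 44, and the position remained tied to the treatment in each.

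The effects at the 2 times, which share no array, were compared across miRNAs. Across the 204 miRNAs above the negative controls on all 12 arrays, the log2 changes at 12 h and 24 h correlated with a Pearson r of 0.905 and a Spearman rho of 0.859, and across all 1507 with 0.545 and 0.311; these are correlations across miRNAs, which are not independent replicates. Across all 1507 the Pearson correlation of the Gal-9 effects was 0.15 with spike scaling and 0.23 with the blank signal subtracted, and 0.80 across the 487 detected on all 12 arrays. Of the calls, 34 were higher at both times, where independent lists would share 1.37, and 12 were lower at both, where 0.327 would be shared. Within the 204 above the negative controls the excess was smaller, with 29 shared higher against 5.80 and 12 shared lower against 2.12. 0 were called in opposite directions. Independence is not a fair reference for these overlaps, since 1 model gave each probe the same SE at both times. All 12 arrays were also normalized together, and odd and even slide positions were tied to treatment at both times. The difference between the effects was tested for each probe by limma and 0 of 1507 were called (smallest adjusted p = 0.823), with 59 at an unadjusted p below 0.05. Among the differences above 0, the smallest unadjusted p-values belonged to miR-2117, miR-6716-3p (log2 difference 0.62), miR-4446-3p, miR-3664-5p and miR-328 (0.51). Among those below 0 they belonged to miR-1915-3p (-0.73), miR-4659a-5p, miR-3960 (-0.64), miR-549a (-0.58) and miR-3128, and adjusted p was 0.823 or 0.974 for these 10 miRNAs. The 5 without a value were not well above background on any array of 1 of the groups. Of the 10, 7 were above the negative controls on 0 arrays, miR-6716-3p and miR-549a among them. Changes of 0.5 were recovered in 27% of simulated cases here, so a moderate difference was often not detectable.

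**Figure D3:**
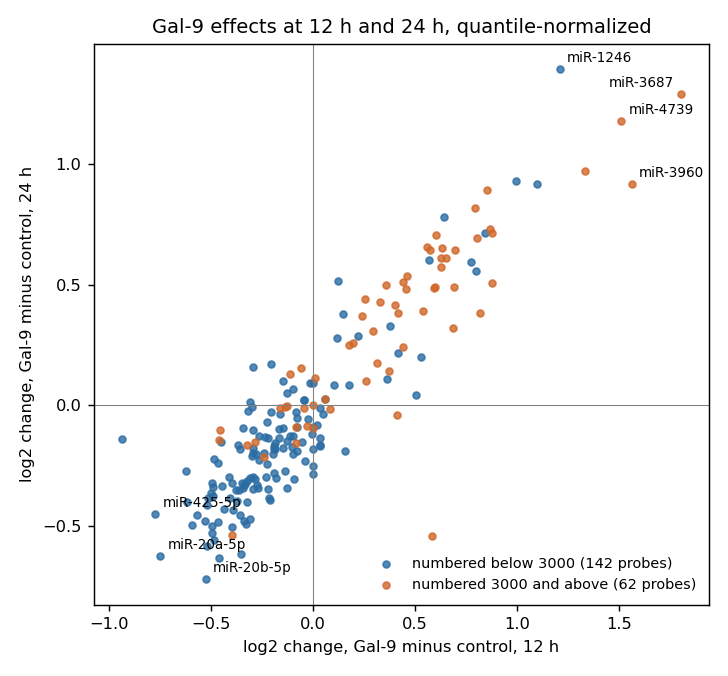
Log2 change, Gal-9 minus control, at 12 h (horizontal axis) and 24 h (vertical axis) for the 204 miRNAs above the negative controls on all 12 arrays (points), 62 of them numbered 3000 and above (orange) and 142 numbered below (blue), after quantile normalization. The changes correlated with a Pearson r of 0.905; scaled to the spike controls, the median over these 204 averaged changes moves from -0.12 to 0.16.

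In control cells no miRNA was called by limma between 24 h and 12 h. miR-1915-3p had the smallest p, with a log2 change of 0.64 (SE 0.13, adjusted p = 0.245), followed among the higher values by miR-625-3p (0.44), miR-5583-5p (0.52), miR-631 (0.47) and miR-549a (0.45). The lower values with the smallest p were miR-1295b-3p, miR-6716-3p (-0.46), miR-4701-3p, miR-3664-5p and miR-518f-5p (-0.48). The 3 without a value were above the blank spots on 0 of 3 control arrays at 24 h. Of these 10 miRNAs, 6 were above the negative controls on 0 arrays, miR-5583-5p, miR-549a and miR-6716-3p among them. 0 of 1507 probes were called by limma, while 160 had an unadjusted p below 0.05, and no list was called. Adjusted over the list alone, 1 member of the stress list and 1 of the X-linked cluster were higher. The groups did not overlap for 16.7% of the probes, where chance gives 10%. The number with an unadjusted p below 0.05 was 236 without control replicate 3 at 12 h, 232 with array weights and 268 with spike scaling, so a difference between the times is not excluded. Scaled to the spike controls, the median of all probes was lower at 24 h (log2 change -0.57 in control cells and -0.49 in Gal-9-treated cells), with 0 calls in either. Between 1351 and 1746 probes per array were above the blank spots at 12 h, against 799 to 1439 at 24 h. With slide and scan date unknown, a technical difference between the arrays of the 2 times is not excluded. With a variance trend and a robust prior 1 probe was called, miR-1915-3p, and without control replicate 3 at 12 h 1 other, miR-150-3p (log2 change 0.82), which was named after its value was seen.

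In Gal-9-treated cells 0 of 1507 probes were called between 24 h and 12 h by limma, with 100 at an unadjusted p below 0.05 and a smallest adjusted p of 0.505. The groups did not overlap for 11% of the probes. The higher values with the smallest p were miR-2117, miR-24-1-5p (log2 change 0.50), miR-33b-3p (0.36), miR-515-5p (0.55) and miR-4443 (0.37). The lower ones were miR-1273f (-0.48), miR-4476, miR-4740-5p (-0.37), miR-4659a-5p and miR-489. The 4 without a value were above the blank spots on no Gal-9 array of 1 of the times. No list was called. 1 member of C19MC was higher adjusted over the list alone. Without Gal-9 replicate 2 at 24 h 1 probe was called, miR-1185-1-3p (log2 change -0.70), which was named after its value was seen.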

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

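The test of slide place, the spike-scaled test and the splits of the samples were chosen after the counts had been seen; the brightness test was not. Of 38 kinds of control spot outside the miRNA probes, 2 with unstated content passed and were brighter on the Gal-9 arrays, averaged over both times: S-Probe1009 by 0.22 (SE 0.05, adjusted p = 0.00963, limma) and S-Probe1014 by 0.29 on the log2 scale (SE 0.08, adjusted p = 0.0279). At the single times S-Probe1009 passed at 12 h (adjusted p = 0.0155) but not at 24 h (0.415), and S-Probe1014 at neither (0.284 and 0.352). Single arrays were not tested for outliers within their groups of 3, and the test of the difference between the Gal-9 effects called 0 probes.

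The pattern weighed here is that, with Gal-9, 48 of 613 miRNAs numbered 3000 and above were called higher and 2 lower (median 0.02, or -0.02 with centring on the median), while members of conserved families were among the 61 called lower. An error that grows with brightness is argued against, since within 5 brightness classes the 62 high-numbered miRNAs above the negative controls on all 12 arrays exceeded the 142 others by 0.508, against 0.506 without classes (means, log2; stratified permutation p = 1e-04, the smallest 10000 permutations can give). The falls may exist only relative to the array-wide scale: the median spike-scaled change of the 61 probes called lower was -0.079 (quartiles -0.14 and 0.01). Odd and even slide places cannot be told apart from treatment, as 0 places held both kinds of array, and a biological effect of Gal-9 and a dependence on probe sequence, which was not used here, stay open beside it.

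For the averaged effect, 1 of 100 splits of the arrays within times, drawn from 200 distinct ones (the real one kept), gave as many calls, with 130 calls against 1 in the highest other split. The other splits mixed Gal-9 and control arrays in their groups, which widens the spread within groups, so few calls were to be expected there. The count sets the real split apart among these arrays. It cannot tell treatment from slide position or measure the spread between cultures. For the change of the effect between times the real split gave 0 calls and 100 of 100 splits gave as many, the highest other 16; a count of 0 is reached by any split, so nothing follows from it. At 12 h the real split gave 82 calls (1 of 10 splits as large) and the highest other 0, and at 24 h 56 calls (1 of 10) and 0. Between the times in control cells the real split gave 0 (10 of 10 as large) and the highest other 1, and in treated cells 0 and 0, from which nothing follows either. 10 splits are too few for a share under 0.05.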

How the results depend on the processing

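Alternatives chosen after seeing the data were those with detection on the mean foreground or against the negative controls, the median foreground, slide position, list names without the arm and spike scaling. The counts of calls were 82 at 12 h, 56 at 24 h, 130 averaged and 0 for the change of the Gal-9 effect, which stayed at 0 in all 29 alternatives. Subtracting the mean blank signal gave 27, 2 and 76. Without background correction 24 h gave 86, and with a trend and robust prior 85. Only probes detected on all 12 arrays gave 131 at 12 h and 99 at 24 h, where fewer probes (487) were tested; detection against the negative controls gave 141 and 105 (319 tested), and detection on the mean foreground 88 at 24 h (642 tested). Only the arrays compared gave 52 at 12 h. Spike scaling, which also subtracts the blank signal and has no quantile step, gave 43, 24 and 66. Only slide positions 1 and 2 gave 41 averaged and only 3 and 4 gave 44, with fewer arrays. A trend and robust prior gave 1 call for the times in control cells. Leaving out single arrays gave 54 to 82 at 12 h, 28 to 49 at 24 h, 104 to 127 averaged, 0 to 0 for the change of the effect, 0 to 1 between times in control cells and 0 to 1 in treated cells. Unless fewer probes or arrays were used, the cause was not tested.

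List medians changed sign under spike scaling at 12 h for let-7 (0.079), miR-17-92 (0.0059), miR-30 (0.049), oncomiRs (0.18) and 14q32 (0.075); at 24 h for miR-23/27/24 (0.037), oncomiRs (0.068) and 14q32 (0.062); and averaged for miR-23/27/24 (0.0087), oncomiRs (0.13) and 14q32 (0.058). Centring on the median turned the median of miRNAs numbered 3000 and above to -0.011, -0.024 and -0.023, though the set test still called them higher. Of 224 alternatives of the 25 called list results, 185 kept call and direction, 25 lost the call and 14 changed sign. Of 1890 alternatives of the 72 named and called results, 1694 kept the call, 196 lost it and 0 reversed, with 37 of the losses under spike scaling and 35 under blank subtraction. The correlation between the times ranged from 0.15 with spike scaling to 0.88 with detection against the negative controls, and from 0.47 to 0.55 leaving out single arrays.

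For Gal-9 and control arrays with equal replicate numbers, the deviations from the group means correlated at 0.25, 0.08 and 0.17 at 12 h. At 24 h they correlated at 0.03, 0.07 and -0.00072. Arrays with unequal numbers were not compared in this way, so a pairing of the arrays, above all at 12 h, is neither shown nor excluded. With the replicate number as a replicate block the counts were 80, 53 and 137, and with a block within time 80, 57 and 139. A block on slide or scan date was not run, because the files used give neither. Signal over background limits the list: 64 of the 82, 48 of the 56 and 103 of the 130 called probes were above the negative controls on all 12 arrays.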

Other observations

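The test on the miR-200 family was chosen after the levels had been seen; that of neighbouring genes was not. Lists not yet described held no calls with Gal-9: C19MC (0 of 17 tested members, camera adjusted p = 0.703 averaged) and the X-linked cluster of miR-506 to miR-514a (0 of 7, and 1 higher adjusted over the list alone, adjusted p = 0.401). The same held for markers of red cells and serum (0 of 4, 0.593), white blood cells (0 of 3, 0.631, with 1 higher at 12 h adjusted over the list alone), fibroblasts and smooth muscle (0 of 5, 0.631) and striated muscle (0 of 2, 0.703). Of the endothelial markers 1 of 2 was lower (miR-126-3p; camera adjusted p = 0.0692, fry 0.0124) and of the neuronal ones 1 of 3 (miR-9-5p; camera 0.195, fry 0.0398). Median, mean and direction of the camera test differed in sign at 12 h for the p53 list (median -0.09, mean 0.0074, test lower) and the stress list (-0.09, -0.18, higher). They also did at 24 h for the stress list (0.05, -0.02, lower), C19MC (-0.03, 0.0071, higher), the X-linked cluster (-0.03, -0.12, higher) and white blood cells (-0.01, 0.0048, higher), none of which passed. The liver marker miR-122-5p was not tested and was above the negative controls on 0 arrays.

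A biologist would look again at the miRNAs these cells did and did not show. miR-200 family members, abundant in most epithelial cells, were seldom above the negative controls: miR-200a-3p and miR-200c-3p passed the negative controls on 2 of 12 arrays each, miR-200b-3p on 1, miR-141-3p and miR-429 on 0. miR-205-5p, on the same list but not of that family, passed them on 1. Against the blank spots the list members did pass, miR-200a-3p and miR-429 on 12 arrays, miR-200b-3p and miR-205-5p on 10, miR-200c-3p on 8 and miR-141-3p on 5. The intestinal miRNAs miR-192-5p, miR-194-5p and miR-375 passed the negative controls on 6, 5 and 2 arrays and the blank spots on 12, 12 and 9. miR-31-5p, miR-125b-5p, miR-100-5p, miR-221-3p and miR-23a-3p passed the negative controls on all 12.

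RNA of the 7 other cell types or fluids with marker lists is neither shown nor excluded: 0 of 21 of their markers on the array passed on all 12, a bound chosen after the levels were seen, but miR-126-3p passed on 11 and miR-9-5p on 8. Low sensitivity of the arrays, a failure of these epithelial probes and a cell population other than the label names may each remain possible; no biological explanation was tested.

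A hypothesis set before its test was that miRNA genes close together changed together with Gal-9. Among 83 of 204 well-measured probes matched to 1 gene, 26 pairs within 10000 bases (shared numbers and the miR-17 seed group left out) differed by 0.12 on average in their averaged log2 change, against 0.45 in random pairs (one-sided permutation p = 0.00020, 10000 permutations). Against random pairs numbered below 3000 (0.39), chosen after the first result, p was 0.00050. The 26 pairs were made of only 18 miRNAs, with both arms of miR-409 counted. 25 of the 26 pairs lie on chromosome 14, so the result may describe 1 cluster, transcribed together, more than neighbours in general. One example outside it is miR-25-3p with miR-93-5p, which fell by 0.51 and 0.47. The miR-23/27/24 clusters gave no pair here, so the p-values do not cover them, and their members changed unequally on the quantile scale. The averaged log2 changes were -0.02 for miR-23a-3p, -0.14 for miR-23b-3p, -0.33 for miR-24-3p, -0.43 for miR-27b-3p and -0.55 for miR-27a-3p. With spike scaling they were 0.01, 0.06, 0.11, -0.11 and -0.20 in the same order (SE 0.16 to 0.19).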
